A study of Rattus norvegicus with 23 samples.

How the data were processed

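Gene expression was measured on 23 single-channel rat expression arrays, 1 per sample of total RNA from primary hippocampal cultures at 12 days in vitro. The sample titles put 9 samples in the aCaN group and 7 in the LacZ group. The titles of the other 7 name neither virus and were taken as the uninfected group by elimination, because the sample descriptions name these 3 conditions. Replicate numbers come from the titles. The title of 1 uninfected sample carries a suffix after its number, which the labels do not explain and which could mark a repeat hybridisation. It was taken as replicate 5 here, also where the replicate number served as a block and where samples with the same number were compared.

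The deposited values are intensity values on a linear scale, 1 per probe set and array, between 0 and 76531.9. The software that made them, its scaling target and any detection calls are not given in the sources used here. The 2% trimmed means of the 23 arrays lay between 1501.65 and 1502.07, so the deposited values had been scaled to a common level, and this scaling was kept. The number of arrays limits the precision of each value. A scaling to a common level cannot show a change in the total RNA of a culture.

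The table held 8799 probe sets, of which 59 control probe sets were left out. In the platform annotation 7006 of the other 8740 probe sets carried 1 gene symbol, 308 several and 1426 none, and only those with 1 symbol were named. Symbols were compared through gene identifiers with a current rat gene table, which left 6985 as they were; 21 without a match kept the annotation's symbol. No probe set was named Gfap or Rcan1 by this annotation, and these genes are not analysed here. Values were turned into log2(intensity + 24.8), where the pseudocount of 24.8 is the 10th percentile of all values, so that log2 differences of dim genes understate the change. Probe sets with a mean log2 value above the 40th percentile were kept, 5244 in all.

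Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with all 23 arrays in 1 model with group as the only term. P-values are two-sided and adjusted by Benjamini-Hochberg over the probe sets kept, and an adjusted p below 0.05 counted as a difference. Of several probe sets of a gene, the one with the highest mean over all samples stood for the gene. Among the named genes that differed, no other probe set of the same gene was called in the opposite direction, and 65 of 66 other probe sets had the same sign in aCaN against LacZ, 62 of 65 in LacZ against uninfected cultures and 55 of 58 in aCaN against uninfected cultures. Folds are 2 to the power of the log2 difference and means are of the deposited intensities. Gene lists, 18 of pathways and gene families and 6 of cell type markers, were tested with limma's camera with a preset inter-gene correlation of 0.01, where at least 5 genes were measured, adjusted over the 23 lists tested. The lists were also tested with a correlation estimated from the data. Of 791 list memberships 554 were on the array. Some genes stand in more than 1 list, such as C3 and Serping1 among reactive astrocyte and complement genes, and neuron and synaptic vesicle lists share 5 measured genes.

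The genes named are, by a rule fixed before the data were examined, the 12 with the largest increase and the 12 with the largest decrease that passed in aCaN against LacZ, 8 and 8 in LacZ against uninfected cultures and 6 and 6 in aCaN against uninfected cultures, up to 4 members of each list with the smallest p, and the calcineurin subunits. The lists, tests and most alternatives were fixed at the same time. The 3' to 5' ratios of control probe sets for beta-actin and Gapdh were compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment over 6 tests.

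The tests were run on simulated data with the real means and spreads of 5244 probe sets, of which 200 were changed. For aCaN against LacZ 34 of 50 probe sets changed by 0.5 on the log2 scale were recovered and 50 of 50 changed by 1, for LacZ against uninfected cultures 39 of 50 and 48 of 50, and for aCaN against uninfected cultures 32 of 50 and 49 of 50. Between 5 and 8 unchanged probe sets were called. In each comparison camera called a list shifted by 0.5 and none of the other lists. The simulated noise was independent between genes, so this does not show how often correlated genes lead to false list calls. Alternatives covered the pseudocount (1, or the 25th percentile, 92.3), the filter (none, or the 60th percentile), the scaling (quantile, or median centring), the samples in the model, array weights, a robust variance model, the replicate number or the style of the titles as a block, 1 value per gene, a threshold of 0.01, leaving out each sample in turn, and the handling of the lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.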

Results

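Gene expression was measured in primary hippocampal cultures from rat at 12 days in vitro. Such cultures hold neurons together with astrocytes and smaller numbers of other glial cells. The cultures were infected with an adenovirus carrying activated calcineurin (aCaN), a form of the calcium-dependent phosphatase, in 9 samples, or with an adenovirus carrying LacZ, a bacterial reporter gene, in 7 samples, or were left uninfected in 7 samples. Each sample was hybridised to 1 rat expression array with 8799 probe sets. The array medians lay between 363.7 and 434.7 intensity units, and the arrays' 2% trimmed means between 1501.65 and 1502.07. After filtering, 5244 probe sets were compared, among them probe sets of 3130 named genes. Arrays of a group correlated with r between 0.953 and 0.990, and arrays of different groups with r between 0.917 and 0.980, both across probe sets, which are not independent replicates. The first principal component, with 26.9% of the variance, separated the uninfected arrays from both virus groups. The second, with 15.4%, separated aCaN from LacZ, and LacZ replicates 1 and 5 lay farthest out on it, at -22.6 and -22.0, against -9.30 to -1.52 for the other LacZ arrays. The log2 ratio of the 3' to the 5' control probe set, a measure of RNA integrity, was 0.21 ± 0.07 (SD, n = 9) in aCaN, 0.17 ± 0.09 (SD, n = 7) in LacZ and 0.23 ± 0.07 (SD, n = 7) in uninfected cultures for beta-actin. None of the 6 differences between groups in this ratio, 3 for beta-actin and 3 for Gapdh, passed an exact two-sided permutation test (adjusted p = 0.954 in all 6). The labels do not say whether the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples.

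The aCaN and LacZ cultures had both received an adenovirus and differed in the gene it carried. Antioxidant, extracellular matrix, complement and astrocyte genes were higher with aCaN than with LacZ, and neuron markers were slightly lower. Gpx1, a glutathione peroxidase, had an intensity of 11898 ± 1941 (SD, n = 9) in aCaN and 2716 ± 583 (SD, n = 7) in LacZ cultures, 4.38-fold higher (log2 difference 2.13, SE 0.13, limma adjusted p = 5.04e-12), and lay above the LacZ mean in 9 of 9 aCaN arrays. Nqo1, a quinone reductase, was 4.0-fold higher (7467 ± 858 against 1865 ± 352), and Hmox1, the inducible heme oxygenase, 2.90-fold (8661 ± 1870.0 against 3002 ± 807). The astrocyte water channel Aqp4 and the gap junction protein Gja1 both rose 3.51-fold.

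In all, 642 of the 5244 probe sets differed between aCaN and LacZ (limma, adjusted p below 0.05), 456 higher and 186 lower in aCaN. Among these, 106 were at least 2-fold higher and 1 was at least 2-fold lower. The share of higher calls depended on the scaling of the arrays: 456 of 642 (71.0%) with the deposited scaling became 383 higher and 241 lower (61.4%) after quantile normalization and 392 higher and 365 lower (51.8%) when each array was centred on its median. Besides Gpx1, Nqo1, Aqp4 and Gja1, the 12 genes with the largest increases were Itgae, an integrin subunit (4.38-fold), the chemokine Ccl20 (4.34-fold), the galectin Lgals1 (4.25-fold), the tetraspanin Cd9 (4.07-fold), Mdfic (3.98-fold), the transcriptional inhibitor Id1 (3.81-fold), Pmp22 (3.79-fold) and the cytokine Il33 (3.28-fold), with limma adjusted p of at most 2.17e-05. The Itgae value rests on 1 probe set, as its other probe sets were too dim to be tested. The decreases were smaller. Lyz2, a lysozyme of macrophages and microglia, fell 2.04-fold (216 ± 67.2 against 461 ± 109.5, limma adjusted p = 3.00e-04). The next largest decreases were in Adra2c (1.84-fold), the netrin receptor gene Unc5a (1.75-fold), Ppp1r16b (1.72-fold), Scarb1 (1.68-fold), the calcineurin-binding protein gene Tesc (1.56-fold), the interferon-induced Rsad2 (1.56-fold), Hsd11b1 (1.56-fold), Ptgs2 (1.55-fold), Hdac2 (1.55-fold), Mas1 (1.53-fold) and the immediate early gene Egr1 (1.53-fold), each lower in at least 7 of 9 aCaN arrays. Of these, 5 calls ended when single samples were left out: Adra2c (without aCaN replicate 2 or 3 or LacZ replicate 1, 7 or 8, adjusted p up to 0.0735), Hdac2 (without LacZ replicate 8, 0.0542), Ptgs2 (without aCaN replicate 1, 2, 3, 4 or 8 or LacZ replicate 1, 5, 6 or 7, up to 0.0940), Rsad2 (without aCaN replicate 3, 4, 5, 6 or 8 or LacZ replicate 1, 2 or 4, up to 0.0834) and Scarb1 (without aCaN replicate 5 or 7 or LacZ replicate 5, up to 0.0667). Adra2c, Hdac2 and Ptgs2 also lost their calls in a fit of the aCaN and LacZ arrays alone (adjusted p of 0.0741, 0.0533 and 0.0803), Adra2c and Ptgs2 without the filter on dim probe sets (0.0517 and 0.0670), and Ptgs2 with array weights (0.102).

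Of the 23 gene lists tested, 12 differed between aCaN and LacZ (limma camera, adjusted p below 0.05). The extracellular matrix list shifted upward most clearly (median log2 difference 0.51, adjusted p = 1.88e-13): of its 29 measured genes 16 rose and 0 fell, and 20 rose adjusted over the list alone. Tenascin C (Tnc) rose 3.15-fold, the fibrillar collagen gene Col5a2 2.84-fold and tissue plasminogen activator (Plat) 2.71-fold. Of 15 astrocyte markers 10 rose and 0 fell, with the same 10 and 0 adjusted over the list alone (median 0.75, adjusted p = 2.63e-09), among them S100b (2.55-fold) and glutamine synthetase, Glul (2.52-fold). Of 34 stress and antioxidant genes 15 rose and 0 fell, against 16 and 1 adjusted over the list alone (adjusted p = 7.72e-07), and the small heat shock protein gene Cryab rose 3.13-fold. Of 8 complement genes 4 rose, also adjusted over the list alone (adjusted p = 0.00199): C3 (2.94-fold), C1s (2.63-fold), C1r (2.58-fold) and the C1 inhibitor Serping1 (2.21-fold). Of 9 endothelial, mural and fibroblast markers 5 rose, 6 adjusted over the list alone (adjusted p = 2.27e-04), including Col3a1 (1.95-fold) and Acta2 (1.94-fold). Of 16 cell cycle genes 5 rose, also adjusted over the list alone (adjusted p = 0.00199), among them the replication gene Mcm6 (1.59-fold), the mitotic kinase gene Cdk1 (1.46-fold) and the cell cycle inhibitor gene Cdkn1a (1.37-fold). Of 19 reactive astrocyte genes 8 rose and 0 fell, 11 and 0 adjusted over the list alone (adjusted p = 1.73e-05), with vimentin (Vim) 2.44-fold and ceruloplasmin (Cp) 2.21-fold higher. This call was lost with an estimated correlation (adjusted p = 0.0661 with an estimated correlation).

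Neuron markers shifted downward (median -0.15, adjusted p = 9.16e-04): 4 of 18 fell and 0 rose, 5 and 0 adjusted over the list alone, with the neurofilament gene Nefh 1.38-fold and Thy1 1.26-fold lower. The calls for Elavl4 and Mapt, also among the 4, ended with array weights. Against uninfected cultures the neuron markers did not shift in aCaN (median 0.004, camera adjusted p = 0.567) or in LacZ (median 0.15, adjusted p = 0.240). Between aCaN and LacZ the cholesterol and sterol list also shifted downward (median -0.15, adjusted p = 0.00212). Of its 19 genes 5 fell, among them Insig1 (1.28-fold), and 2 rose, including Apoe (2.43-fold), a lipid carrier that is also an astrocyte marker. Adjusted over the list alone 9 fell and 2 rose. Downward shifts of 3 further lists were lost with an estimated correlation. Quantile normalization also ended the calls for oxidative phosphorylation (adjusted p = 0.0725) and ribosomal proteins (adjusted p = 0.541), and the latter ended without aCaN replicate 1 (adjusted p = 0.0585) and without LacZ replicates 1 and 5 together (adjusted p = 0.0555). The 3 lists were oxidative phosphorylation (2 of 29 fell and 1 rose, the same adjusted over the list alone, adjusted p = 0.00199, and adjusted p = 0.163 with an estimated correlation), synaptic vesicle release (2 of 25 fell and 1 rose, 4 and 1 adjusted over the list alone, adjusted p = 0.00759, and adjusted p = 0.0986 with an estimated correlation) and ribosomal proteins (2 of 35 fell, 1 adjusted over the list alone, adjusted p = 0.0111, and adjusted p = 0.426 with an estimated correlation). The other 8 shifts held with an estimated correlation. Only the extracellular matrix list passed clearly there (camera adjusted p = 9.20e-04), and the rest lay near the threshold, with adjusted p of 0.0417 or 0.0450. The lists for the calcineurin and NFAT pathway, inflammation and NF-kB, interferon response and antigen presentation, the glutamate synapse, GABA and interneurons, calcium channels, immediate early genes, glycolysis, Alzheimer related genes, microglia and macrophages, and the oligodendrocyte lineage did not pass, with adjusted p from 0.125 to 0.959. The ependymal and choroid plexus markers had 4 measured genes, fewer than the 5 needed for a test, and 1 of them, Foxj1, rose 1.76-fold. The brightest probe sets for 3 calcineurin subunits did not pass between aCaN and LacZ: the log2 difference was -0.11 for Ppp3ca, -0.06 for Ppp3cb and -0.13 for Ppp3r1 (adjusted p of 0.402, 0.828 and 0.532), but a second, dimmer Ppp3r1 probe set was lower in aCaN (log2 difference -0.42, adjusted p = 0.0202). With array weights Ppp3ca passed, at -0.18 (adjusted p = 0.0433). As these rat probe sets may not detect the virus-borne calcineurin, they are no test of its expression. Without LacZ replicates 1 and 5, a choice made after seeing the data, 466 probe sets differed, 362 higher and 104 lower in aCaN, in place of 456 and 186. Adra2c, Elavl4, Mapt, Rsad2, Scarb1 and Ptgs2 among the genes above no longer passed.

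**Figure D1:**
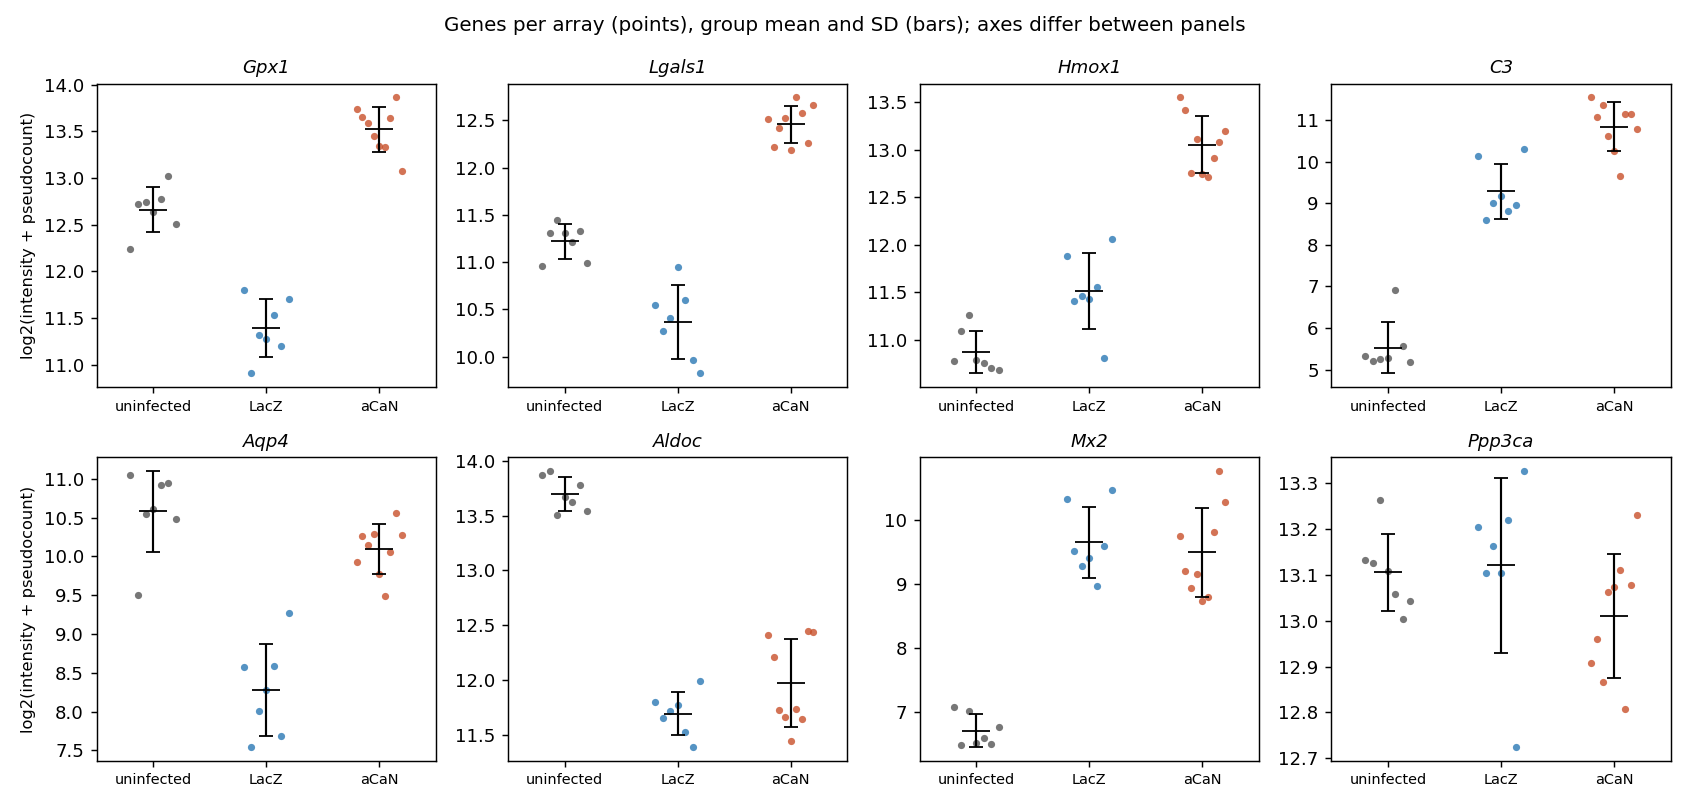
Each panel plots 1 gene, with the log2 of intensity plus pseudocount on the vertical axis and the 3 groups on the horizontal axis; points are arrays, and bars give the group mean and SD. Gpx1, Lgals1, Hmox1 and C3 lie highest in aCaN, Aldoc and Aqp4 lie lower in LacZ than in uninfected cultures, Mx2 is high in both virus groups, and Ppp3ca overlaps between all 3 groups.

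Infection with the LacZ virus was set against no infection, which combines the effects of the vector, its handling and the LacZ gene it carried. Astrocyte markers were lower in the LacZ cultures. Interferon response genes were higher, but this list shift was lost with an estimated correlation (adjusted p = 0.177) and with a filter at the 60th percentile (adjusted p = 0.126). The cytokine gene Il33 fell 15.0-fold, from 1942 ± 292 (SD, n = 7) in uninfected to 111 ± 40.8 (SD, n = 7) in LacZ cultures (log2 difference -3.91, SE 0.21, limma adjusted p = 3.37e-13). The interferon-induced Rsad2 rose 9.52-fold (1836 ± 554 against 172 ± 62.9) and Mx2 7.69-fold (834 ± 350.3 against 81.3 ± 19.6). The complement gene C3 rose from 26.3 ± 30.7 to 662 ± 353 and the siderophore-binding Lcn2 from 82.7 ± 55.0 to 1209 ± 1067 (log2 differences 3.75 and 3.35). C3 lay near the pseudocount in uninfected cultures, and its log2 difference was 4.89 with a pseudocount of 1 and 2.58 with one at the 25th percentile, where Lcn2 had 2.62 and Mx2 2.34.

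Of the 5244 probe sets, 1292 differed between LacZ and uninfected cultures, 652 higher and 640 lower in LacZ (limma, adjusted p below 0.05), 37 of them at least 2-fold higher and 163 at least 2-fold lower. The largest increases further included the histone genes Hist4h4 (5.62-fold) and Hist1h2ao (4.50-fold), the guanylate-binding protein gene Gbp2 (4.27-fold) and the chemokine Cxcl10 (4.09-fold). The largest decreases further included the fatty acid binding protein of radial glia and astrocytes, Fabp7 (6.03-fold), matrix Gla protein, Mgp (5.88-fold), latexin, Lxn (5.66-fold), the thioesterase Acot1 (5.57-fold), Cd48 (5.21-fold), Pmp22 (5.17-fold) and S100b (5.03-fold).

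The astrocyte markers shifted downward (median log2 difference -1.84, camera adjusted p = 6.72e-16): 13 of 15 fell and 0 rose, with the same counts adjusted over the list alone. Aldolase C (Aldoc) was 4.01-fold lower, Glul 3.58-fold, Apoe 3.74-fold and metallothionein 3 (Mt3) 2.21-fold. The extracellular matrix list moved with them: 14 of its 29 genes fell and 2 rose, 16 and 2 adjusted over the list alone (median -0.35, adjusted p = 3.35e-06), with brevican (Bcan) 4.72-fold, Serpine2 3.64-fold and Plat 3.14-fold lower. These 2 shifts held with an estimated correlation (camera adjusted p = 0.0291 for both) and 3 others did not. Interferon response and antigen presentation genes shifted upward, with 12 of 19 higher and 0 lower, also adjusted over the list alone (median 0.38, adjusted p = 2.58e-05, and adjusted p = 0.177 with an estimated correlation), including Oas1a (1.81-fold). Stress and antioxidant genes shifted downward, with 10 of 34 lower, among them the glutathione transferase Gsta1 (4.12-fold) and Gpx1 (2.41-fold), and 6 higher; adjusted over the list alone 14 were lower and 8 higher (adjusted p = 0.0258, and adjusted p = 0.627 with an estimated correlation). Ribosomal protein genes shifted upward, with 7 of 35 higher, also adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.627 with an estimated correlation). The remaining 18 lists did not pass, with adjusted p from 0.0641 to 0.928. Of 18 neuron markers 3 rose and 1 fell. The ribosomal call ended without LacZ replicate 5 (0.0530), without uninfected replicate 3 (0.0758), with array weights (0.0630) and with quantile normalization (0.0520), and the stress call without LacZ replicate 5 (0.0534) or uninfected replicate 8 (0.0576). Without LacZ replicate 5 the number of shifted lists went from 5 to 3, and 30 of 100 groupings of the same arrays, the real one included, gave at least 5.

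**Figure D2:**
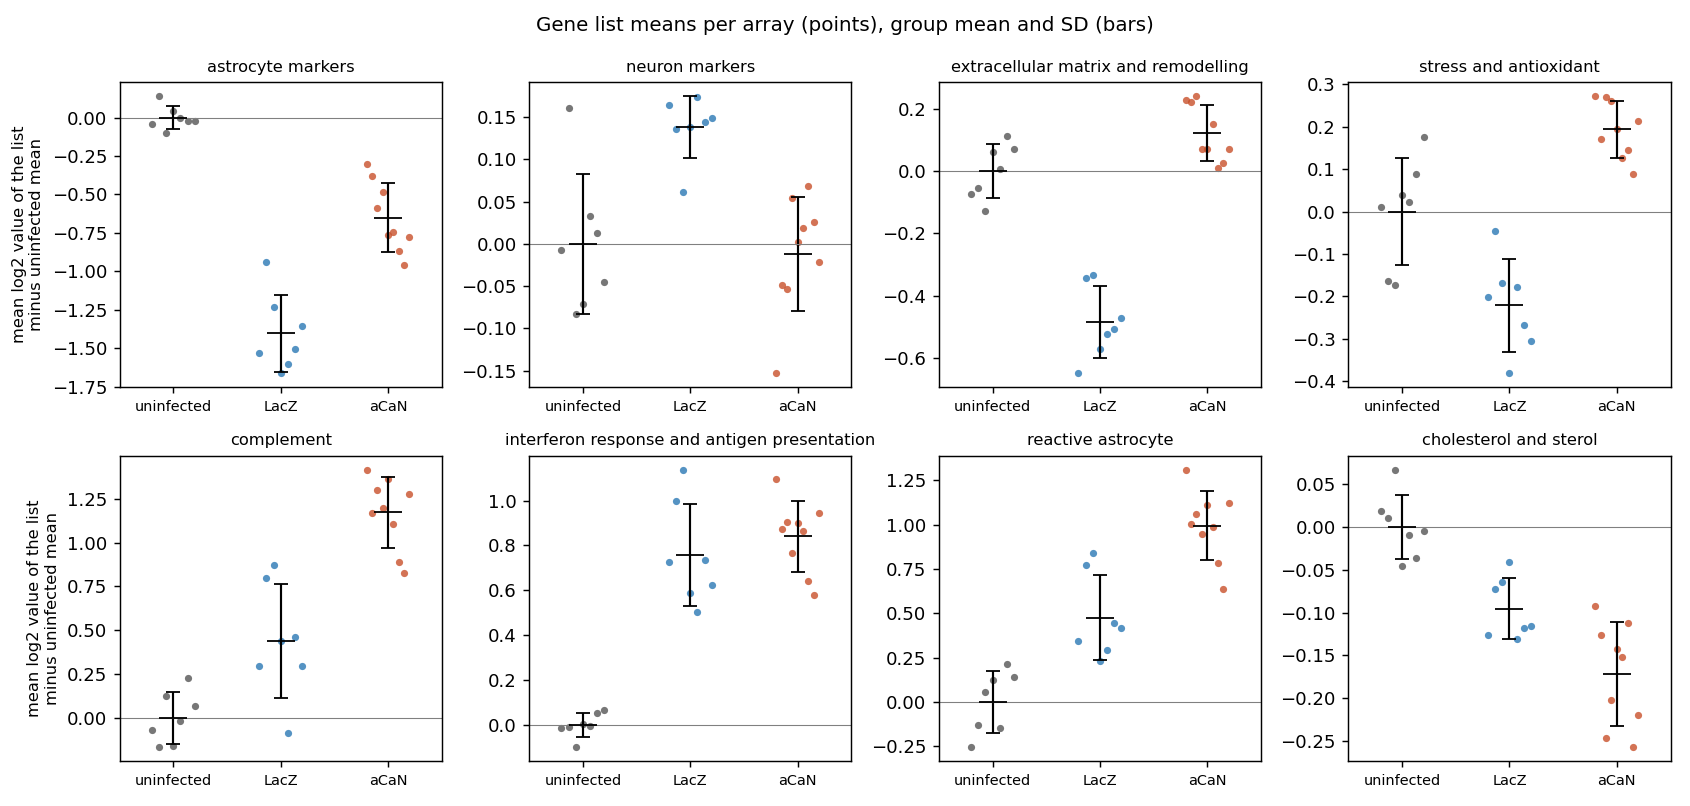
Each panel plots 1 gene list, with the mean log2 value over its measured genes minus the uninfected mean on the vertical axis (log2 units) and the 3 groups on the horizontal axis; points are arrays, and bars give the group mean and SD. Astrocyte markers lie at -1.40 ± 0.25 in LacZ and -0.65 ± 0.23 in aCaN, and the interferon list at 0.76 ± 0.23 and 0.84 ± 0.16.

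The aCaN cultures were also set against the uninfected cultures, which combines the virus with the gene it carried. C3, the chemokine gene Ccl20 and the interferon-induced Mx2 and Rsad2 were higher in aCaN, and Il33 lower. The shifts of the complement, interferon and astrocyte lists did not hold with an estimated correlation (adjusted p = 0.101 for each). C3 rose from 26.3 ± 30.7 (SD, n = 7) in uninfected to 1932 ± 688 (SD, n = 9) in aCaN cultures (log2 difference 5.31, SE 0.29, limma adjusted p = 4.29e-13), or by 6.49 and 4.04 on the log2 scale with the same 2 pseudocounts. Lcn2 rose from 82.7 ± 55.0 to 2223 ± 855, and Ccl20 from 87.0 ± 17.1 to 1418 ± 836 (log2 differences 4.47 and 3.52, or 3.68 and 2.91 with the pseudocount at the 25th percentile). Mx2, Rsad2 and Hist4h4 were 6.90-fold, 6.11-fold and 6.06-fold higher. The largest decreases were in Il33 (4.59-fold), Bcan (3.58-fold), the glucocorticoid-activating enzyme gene Hsd11b1 (3.53-fold), Mgp (3.50-fold), securin, Pttg1 (3.42-fold), and the oxysterol hydroxylase gene Cyp7b1 (3.32-fold).

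Between aCaN and uninfected cultures 1279 of 5244 probe sets differed, 690 higher and 589 lower in aCaN (limma, adjusted p below 0.05), with 86 at least 2-fold higher and 54 at least 2-fold lower. The majority turned with the scaling, to 623 higher and 661 lower after quantile normalization and 567 higher and 722 lower with median centring. Of 23 lists 6 shifted, and none of the 6 held with an estimated correlation. Astrocyte markers shifted downward, with 10 of 15 lower and 0 higher, 12 and 0 adjusted over the list alone (median -0.56, adjusted p = 1.10e-07, and adjusted p = 0.101 with an estimated correlation), and Aldoc was 3.31-fold and the bicarbonate transporter gene Slc4a4 3.14-fold lower. Interferon response and antigen presentation genes shifted upward, with 12 of 19 higher, also adjusted over the list alone (adjusted p = 1.08e-06, and adjusted p = 0.101 with an estimated correlation), including Irf7 (4.84-fold). Reactive astrocyte genes shifted upward, with 10 of 19 higher and 1 lower, 11 and 1 adjusted over the list alone (adjusted p = 1.10e-04, and adjusted p = 0.17 with an estimated correlation). The reactive astrocyte list shares 3 measured genes with the interferon list and 2 with the complement list, so their upward shifts are not independent. Complement genes shifted upward, with 4 of 8 higher, also adjusted over the list alone (adjusted p = 0.00596, and adjusted p = 0.101 with an estimated correlation). Inflammation and NF-kB genes shifted upward, with 6 of 18 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.0308, and adjusted p = 0.348 with an estimated correlation), among them the monocyte chemokine Ccl2 (5.51-fold) and the adhesion molecule Icam1 (3.01-fold). Cholesterol and sterol genes shifted downward, with 6 of 19 lower, also adjusted over the list alone (adjusted p = 0.00596, and adjusted p = 0.101 with an estimated correlation). The other 17 lists did not pass, with adjusted p from 0.0574 to 0.942. The complement and inflammation calls ended without the filter on dim probe sets (adjusted p = 0.430 for both), and the reactive astrocyte and inflammation calls with a filter at the 60th percentile (adjusted p = 0.274 for both). With that filter 3 lists shifted in place of 6, and 20 of 100 groupings of the same arrays, the real one included, gave at least 6.

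Set against both controls together, single genes such as Nqo1, Hmox1, Col5a2 and C3 were higher in aCaN cultures, while the antioxidant and extracellular matrix lists did not shift against uninfected cultures (adjusted p = 0.462 and 0.820). In all, 237 probe sets differed the same way from LacZ and from uninfected cultures, 161 higher and 76 lower in aCaN. Another 103 differed in opposite directions. After quantile normalization the split was 129 higher and 109 lower, and with median centring 135 higher and 149 lower. Both comparisons share the aCaN arrays. Simulated data in which aCaN equalled one of the controls gave at most 1 such probe set in 30 draws. There 1 of the 2 comparisons held no true difference, so a low count was fixed in advance and does not measure the effect of the shared arrays. Independent lists of the same lengths would share 60 higher and 20.9 lower probe sets. With 5 aCaN arrays set against LacZ and the other 4 against uninfected cultures, so that no aCaN array served in both, the median count was 136. Each comparison then held fewer aCaN arrays and had less power, so the fall from 237 does not measure the effect of the shared arrays alone. The 60 and 20.9 belong to the full comparisons and are no expectation for this split. By the size of both differences, and so chosen after the values were seen, 14 genes were at least 2-fold higher in aCaN than in each control: Anxa2, C1s, C3, Ccl20, Col5a2, Cp, Hmox1, Itgae, Lbh, Lgals1, Mdfic, Mmp3, Nqo1 and Tnc. Nqo1 was 4.0-fold and 3.07-fold above LacZ and uninfected cultures, Hmox1 2.90-fold and 4.55-fold, and Col5a2 2.84-fold and 2.41-fold. Egr1, Lyz2 and Tesc were among the genes lower in aCaN than in both. Of the 642 probe sets that differed between aCaN and LacZ, 379 also differed between LacZ and uninfected cultures. In 331 of these 379 the directions were opposite, and in 268 the probe set was lower in LacZ than in uninfected cultures and higher in aCaN than in LacZ. Both comparisons contain the LacZ arrays, whose chance deviations enter them with opposite sign. In a check chosen after seeing the data, 4 LacZ arrays were set against aCaN and the other 3 against uninfected cultures, in all 35 ways: a median of 230.0 probe sets differed in both comparisons and a median of 202 in opposite directions (median share 87.6%, 82.7% to 94.1%).

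**Figure D3:**
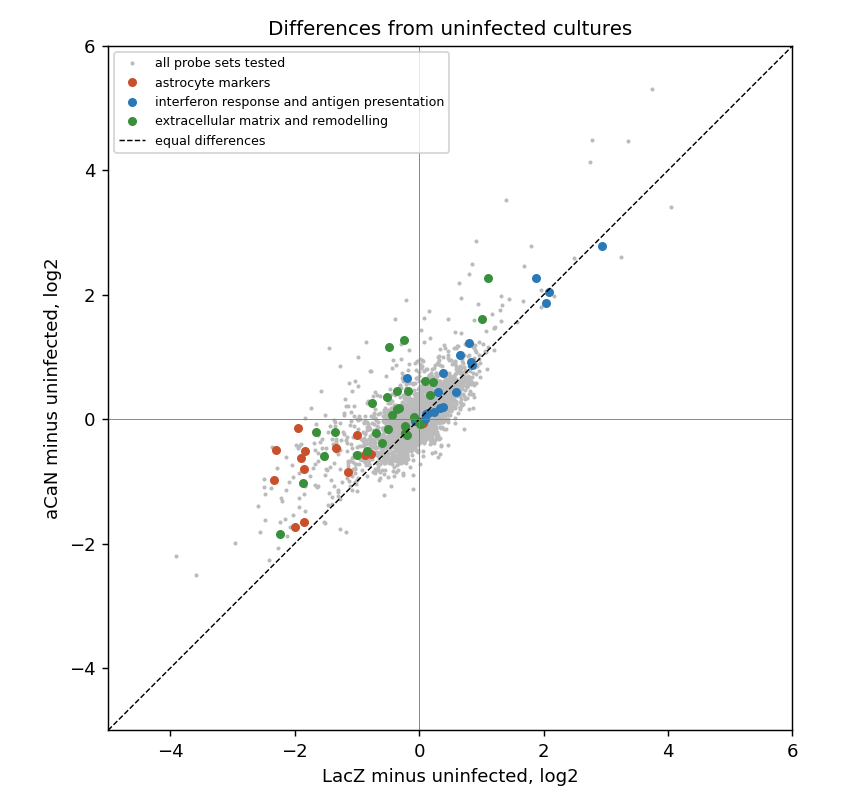
Each point is a probe set, with the log2 difference of LacZ from uninfected cultures on the horizontal axis and that of aCaN from uninfected cultures on the vertical axis; colours mark the measured genes of 3 lists and the dashed line marks equal differences. Most astrocyte markers lie left of 0 and above the line, and interferon genes lie along it at the upper right.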

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

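The tests of technical explanations for the astrocyte genes and for the genes above both controls were chosen after the result was seen, and the counts over other groupings of the arrays were planned.

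In 30 of 327 groups of 7 or 9 arrays, 1 array lay far from the others in a reported gene or list, by its gap to the nearest array over the range of the group. Chance flags about 1 in 20 groups, and genes measured on the same arrays are not independent. LacZ replicate 1 was the far array in 4 of the 30 and uninfected replicate 4 in 3. In uninfected arrays the ratios were 0.635 for Aqp4 (replicate 4 lowest), 0.587 for Ppp3r1 (replicate 4 lowest), 0.783 for C3 (replicate 7 highest), 0.592 for Gbp2 and 0.609 for Hist1h2ao (replicate 5 lowest in both), 0.764 for Oas1a and 0.736 for Scarb1 (replicate 8 lowest in both), 0.579 for Tac1 (replicate 2 highest) and 0.573 for the glutamate synapse list (replicate 4 lowest). In LacZ arrays they were 0.751 for Col5a2, 0.771 for Lbh and 0.631 for Ppp3ca (replicate 1 lowest in all 3), 0.629 for the oxidative phosphorylation list (replicate 1 highest), 0.612 for Gja1 (replicate 2 highest), 0.610 for Thy1 (replicate 2 lowest), 0.631 for Anxa2 (replicate 4 highest), 0.660 for the neuron markers (replicate 4 lowest), 0.657 for Scarb1 (replicate 5 highest) and 0.723 for the calcineurin and NFAT pathway (replicate 5 lowest). In aCaN arrays they were 0.594 for Adra2c (replicate 5 lowest), 0.774 for Cryab and 0.610 for the cell cycle list (replicate 2 lowest in both), 0.513 for Hist4h4 (replicate 4 highest), 0.535 for Plat (replicate 4 lowest), 0.532 for Rsad2 (replicate 1 highest), 0.746 for the oligodendrocyte lineage markers (replicate 1 lowest), 0.505 for Scarb1 (replicate 9 lowest), 0.511 for Top2a (replicate 7 lowest), and 0.526 for the calcineurin and NFAT pathway and 0.498 for inflammation and NF-kB (replicate 8 lowest in both).

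Other groupings of the same arrays were counted, 100 for each result with the real one included. For probe sets, 1 of 100 gave as many as the real 642 in aCaN against LacZ (highest other 263), 1 of 100 as many as 1292 in LacZ against uninfected cultures (highest other 396) and 1 of 100 as many as 1279 in aCaN against uninfected cultures (highest other 539), so no other grouping drawn reached these 3 counts. The groupings treat the arrays as independent, which the labels do not state, so a culture or batch difference between the groups is not excluded. For the 237 that differed the same way from both controls 1 of 100 gave as many (highest other 0), but groupings of all 23 arrays mix the virus effect into every group, so this speaks only against no difference at all. For gene lists, 4 of 100 gave as many as 12 in aCaN against LacZ, a share under 0.05, but the highest other, 14, was above the real count. Chance is not excluded for the number of lists in LacZ against uninfected cultures, where 30 of 100 gave at least 5 (highest other 8), or in aCaN against uninfected cultures, where 20 of 100 gave at least 6 (highest other 14).

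Astrocyte markers lay below the uninfected level with LacZ and less far below it with aCaN. A lower virus load in the aCaN cultures would have weakened the interferon response as well, if activated calcineurin itself left that response unchanged, which was not tested. The aCaN cultures kept 1.11 (SE 0.149) of the interferon effect of LacZ and 0.464 (SE 0.0626) of the astrocyte effect, a difference of 0.646 (SE 0.193). Under that condition these values argue against a lower virus load as the whole cause. However, Rsad2, which is not in that list, rose less with aCaN (2.61 against 3.25 on the log2 scale), and a saturated interferon response was not tested. A smaller share of astrocytes in the LacZ cultures would return all markers by the same fraction, but over 13 markers this ran from 0.0652 (Slc4a4) to 0.860 (Gja1), with an SD of 0.244 against a bootstrap median of 0.0618 (bootstrap p = 0.00150, n = 13 markers, 2000 draws), which argues against it as the whole cause. The median difference between aCaN and LacZ was 0.75 with the deposited scaling, 0.69 with median centring and 0.80 with quantile normalization. The lower thus kept 0.924 of it, and the choice among these scalings does not make the difference. Each of them brings the arrays to a common level, so none can show a change in total RNA. A partial change in cell numbers stays open, as does an effect of activated calcineurin on some astrocyte genes, for which no test was made. This design cannot tell an effect of the LacZ gene apart from that of the virus.

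For the 14 genes at least 2-fold higher in aCaN than in both controls, a change in other cell types was weighed. More endothelial, mural or fibroblast cells in the aCaN cultures may contribute: of 9 markers, 1 of them (Igf2) also in the ependymal list, 5 were higher than in LacZ (median 0.58, camera adjusted p = 2.27e-04) and 3 higher than in uninfected cultures (median 0.372, adjusted p = 0.0971), with Col1a1 at 3972 against 1945 and Acta2 at 4228 against 2169 in LacZ, so this explanation stays open. Against uninfected cultures the Acta2 call (log2 difference 0.69, limma adjusted p = 0.0307) ended when single arrays were left out (up to 0.0898, without uninfected replicate 2). Col1a1 was lower in LacZ than in uninfected cultures, so part of its gap between aCaN and LacZ may lie in LacZ. That call ended without LacZ replicates 1 and 5, and it did not pass when adjusted over the list alone. For microglia or macrophages, the 6 measured markers had a median difference of -0.0035 from LacZ and -0.17 from uninfected cultures, 0 were higher and 1, Lyz2, was lower than in both, which argues against more of them, although the markers were dim (means of 216 to 745). Without LacZ replicates 1 and 5, 14 of 14 genes still passed, with a median difference of 1.38 against 1.55 and a lowest of 1.01. These 2 arrays alone thus do not make the differences. The other LacZ arrays had served to choose the 14 genes, so passing was likely. Over all probe sets the same removal took the calls in aCaN against LacZ from 642 to 466. An effect of activated calcineurin on these genes also stays open and was not tested apart from cell numbers.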

How the results depend on the processing

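The fits without LacZ replicates 1 and 5, without these and uninfected replicate 5, and with the array's 10th percentile of signal as a covariate were chosen after seeing the data; the other alternatives were fixed before. No gene or list called here reversed under the alternatives that gave it a value. Of 323 calls of named genes 276 did not end under any alternative applied to them other than leaving out single samples. Under leaving out each sample 285 did not end, and of 23 list calls the numbers were 10 and 20. The settings with 1 value per gene and with the stricter threshold gave counts of probe sets only and were not applied to these calls. A call without a value under a setting counted as kept there. With the filter at the 60th percentile 387 of 540 results of named genes, called or not, and 21 of 23 list calls had a value.

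Counts of probe sets moved by over 1.5 times with 1 value per gene (410 for aCaN against LacZ, in place of 642, and 843 for aCaN against uninfected cultures, in place of 1279) and at an adjusted p below 0.01 (386, 807 for aCaN against uninfected cultures, and 844 for LacZ against uninfected cultures, in place of 1292), where fewer values or a stricter threshold show the cause. With an estimated correlation 0 lists shifted in aCaN against uninfected cultures (limma camera, in place of 6) and 2 in LacZ against uninfected cultures (in place of 5). With the filter at the 60th percentile 3 shifted in aCaN against uninfected cultures, and the cause was not tested. Dim genes and some lists have no value under that filter, and signal over background limits the log2 differences of genes near the pseudocount, such as C3.

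Leaving out each sample gave 545 to 671 probe sets for aCaN against LacZ (lowest without LacZ replicate 1), 1163 to 1315 for LacZ against uninfected cultures, 1166 to 1379 for aCaN against uninfected cultures and 205 to 238 for both controls. Lists numbered 11 to 13, 3 to 6 (3 without LacZ replicate 5, and the cause was not tested) and 6 to 9. The beta-actin ratio differed by 0.0190 to 0.0550 for aCaN against LacZ, -0.0736 to -0.0369 for LacZ against uninfected cultures and -0.0339 to 0.0038 for aCaN against uninfected cultures, and the Gapdh ratio by -0.0163 to 0.0114, -0.0120 to 0.0286 and -0.0134 to 0.0272.

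With the replicate number as a block, 614, 1410 and 1408 probe sets differed in these comparisons, 555, 1196 and 1195 of them also without the block, 231 differed the same way from both controls, and 11, 5 and 6 lists shifted. The block ended the list calls for inflammation and NF-kB in aCaN against uninfected cultures (adjusted p = 0.0763) and for ribosomal proteins in aCaN against LacZ (0.0583). As 6 lists still shifted in aCaN against uninfected cultures, another list, not identified here, passed only with the block. The labels do not say that equal numbers mark a shared culture. Of 20 pairs with the same number 13 had a correlation over 0.1 (-0.11 to 0.53, median 0.15, against -0.02 for other numbers), and 7 of 22 arrays lay closest to an array of their own number. The count expected for unrelated numbers was not computed. The lowest 10th percentiles of signal fell in replicates 6, 7 and 8 of every group, so a source shared by equal numbers is not excluded.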

Other observations

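The neuropeptide, histone and cell cycle values here belong to lists or ranks fixed before the data were examined, and the 2 tests against the within-group axis were chosen after the result was seen.

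Hist4h4 and Hist1h2ao, 2 histone genes, and Mcm6 rose with either virus, while Top2a, Cdk1 and Ccnd2 fell. The cell cycle list, which holds Mcm6, Top2a, Cdk1 and Ccnd2, did not shift against uninfected cultures: of its 16 genes 2 were higher and 5 lower in LacZ (adjusted p = 0.285), and 6 higher and 4 lower in aCaN (adjusted p = 0.942), and no list of histone genes was tested. Hist4h4 had an intensity of 436 ± 59.0 (SD, n = 7) in uninfected, 2606 ± 609 (SD, n = 7) in LacZ and 2767 ± 389 (SD, n = 9) in aCaN cultures, and Hist1h2ao 353 ± 67.4, 1654 ± 121 and 1439 ± 112. Mcm6, part of the replication helicase, was 2.49-fold higher in LacZ than in uninfected cultures and 3.96-fold higher in aCaN (limma adjusted p = 1.39e-07 and 7.39e-11, above the uninfected mean in 7 of 7 and 9 of 9 arrays). The topoisomerase gene Top2a was 2.77-fold and 2.61-fold lower, the mitotic kinase gene Cdk1 3.12-fold and 2.14-fold lower, and the cyclin gene Ccnd2 2.69-fold and 1.71-fold lower (below the uninfected mean in 7 of 7 LacZ and 9 of 9 aCaN arrays for each).

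Tac1, the substance P precursor, was 2.47-fold higher in LacZ than in uninfected cultures and 3.38-fold higher in aCaN, while cholecystokinin (Cck) was 1.25-fold and 1.53-fold lower. The enkephalin precursor Penk was 1.76-fold higher in aCaN than in LacZ cultures (1353 ± 79.3 against 766 ± 113, above the LacZ mean in 9 of 9 arrays) and 1.24-fold lower in LacZ than in uninfected cultures (limma adjusted p = 0.0185, but 0.0576 in a fit of these 2 groups alone). The lysosomal protease Ctss, a microglia marker, was 2.88-fold lower in LacZ and 3.15-fold lower in aCaN than in uninfected cultures, and the stress-induced transcription factor gene Atf3 2.31-fold and 2.77-fold higher.

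After group means were removed, 1 axis held 24.7% of the remaining variance. Its score fell with the array's 10th percentile of signal (r = -0.893 over 23 arrays, permutation p = 1e-05, the smallest that the permutations can give, rho = -0.909), and r was -0.93, -0.92 and -0.93 within aCaN, LacZ and uninfected arrays. Without the 2 arrays farthest out in the 10th percentile r was -0.904. A candidate explanation is a difference in low-end signal between hybridisations, which these values fit, though both measures come from the same arrays. The beta-actin 3' to 5' ratio had r = 0.425 (p = 0.0438) and rho = 0.414 (p = 0.0511), and r = 0.389 without the 2 arrays farthest out in this ratio (p = 0.0823), and r was 0.33 in aCaN, 0.82 in LacZ and -0.01 in uninfected arrays. The pooled value thus rests mainly on LacZ, and RNA integrity cannot be told apart from other sources with groups of 7 to 9 arrays. In LacZ the beta-actin ratio was lowest in replicates 1 and 5 (0.041 and 0.047), against 0.179 to 0.258 in the other LacZ arrays. The 10th percentile was lowest in replicates 6, 7 and 8 of every group. It was 22.3, 19.3 and 20.2 in aCaN, 19.9, 21.2 and 18.2 in LacZ, and 21.6, 21.2 and 22 in uninfected arrays. Low-end signal thus ran in part with the replicate number, and the labels do not say what equal numbers share. No biological explanation was tested, as the labels give none within a group.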
